A study of Homo sapiens with 9 samples.

How the data were processed

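Binding of p300, a histone acetyltransferase and transcriptional coactivator found at promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing in PC3 cells, a line established from a metastatic human prostate carcinoma. Cells received either no drug or 30 µM MnTE-2-PyP, a manganese porphyrin that mimics superoxide dismutase, for 24 h. Both groups were then irradiated with 20 Gy and fixed in 1% formaldehyde 1 h later, per the labels' protocols. Chromatin was sheared to fragments of about 100 to 300 bp, precipitated with an antibody against p300 and sequenced on the Ion Proton platform, per the labels' protocols. There were 2 untreated and 3 treated p300 libraries, described as biological replicates, and 4 input libraries for which no processed values were used here.

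The authors deposited 1 peak list for each p300 library, so peaks were called per library and not on pooled replicates. Reads were placed on hg19 and peaks were called with MACS2, per the submitters' processing notes. The aligner, the MACS2 version, the threshold and the input library set against each sample are not given in the sources used here. Each deposited list holds the chromosome, start and end of every peak, a peak name and a score per peak. The scale of the deposited score is named neither by the labels nor by the lists, so the score was used only to rank or filter peaks. The lowest score was 3.04 in both lists numbered 1, against 2.02 in untreated list 2, 2.02 in treated list 2 and 2.16 in treated list 3, so the lists may not share one threshold. Read depth is unknown, because the lists hold no read counts. Deeper libraries, or libraries with a better pull-down, usually give more peaks, so a number of peaks measures binding and yield together.

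The peak names carry run identifiers. Untreated list 1 and treated list 1 share one identifier, untreated list 2 and treated list 3 share another, and treated list 2 has its own. These identifiers were read from the names and are not described as batches in the labels. Values within these 2 pairs are given beside the pooled ones for the number of peaks and the length covered, and their mean for the median width.

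No annotation of hg19 was used. The gene table at hand is for GRCh38, a different build from that of the lists, so its coordinates were not used. The results planned on promoters, on genes with a peak within 5 kb of their start and on 11 preset gene lists were therefore not run, and peaks at EP300 and HIF1A were not analysed here. Regions are named by their hg19 coordinates, counted from 1.

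The unit of comparison was the peak list. The number of peaks, the length covered and the median width were compared between groups with an exact two-sided permutation test over the 10 splits of the 5 lists into 2 and 3, whose smallest possible p is 0.2. Overlap of a pair of lists was the percentage of peaks of the shorter list that overlapped a peak of the other by 1 bp or more, with a 95% Wilson interval that covers counting error only. Same-group and between-group overlap were compared with an exact one-sided permutation test, whose smallest possible p is 0.1. Peaks of all lists that overlapped by 1 bp or more were merged into regions, and each region was described by the lists that held it. At the level of a single region, Fisher's exact test for 2 against 3 lists cannot go below 0.1, so no region was tested alone. Region counts were set against the same counts for the other 9 choices of 2 lists, against 100 random placements of every peak on its own chromosome, and against 100 sets in which every peak was shifted at random by up to 500 kb. The shifted sets keep the broad density of peaks along each chromosome. Chromosome length was taken as the span from the first to the last peak of any list. Regions found in all 5 lists and lying within 50 kb of one another were called clusters.

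The named regions followed a rule fixed before the data were examined. It takes up to 10 regions in all 5 lists, up to 10 in both untreated and no treated list and up to 10 in all 3 treated and no untreated list, ordered by the mean percentile of the peak score within its list, and the highest-scoring peak of each list. The settings varied were a score minimum at the pooled median of 5.9, equal numbers of top-scoring peaks (528 per list), a required overlap of 50% of the shorter peak, merging within 500 bp, autosomes and X only, leaving out each list in turn, the replicate number as a block, and group medians. Pairing by run identifier, one common score minimum of 3.04 and the removal of clustered regions were added after seeing the data. The region counting was tested on simulated data, where 100% of 870 planted regions were recovered with their pattern of lists. The planted regions lay far apart and their peaks overlapped by design. The result therefore checks the counting and says nothing on the merging of clustered peaks. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.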

Results

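The series asked where p300 sat in irradiated PC3 cells with and without MnTE-2-PyP. The 5 lists held 19861 peaks in all. The untreated lists held 2313 and 2039 peaks, and the treated lists held 4922, 10059 and 528. The authors' median peak score was 8.05 and 5.25 in the untreated lists and 7.23, 4.89 and 7.42 in the treated lists. Read depth behind these peaks is unknown.

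p300 peaks were 2.38-fold more numerous on average after MnTE-2-PyP, at 5170 ± 4770 per list (SD, n = 3) against 2176 ± 194 without it (SD, n = 2). This difference was smaller than the spread among the treated lists, which differed up to 19.1-fold from one another, while the untreated lists differed 1.13-fold. The exact two-sided permutation test gave p = 0.6. The length covered was 632 and 890 kb in the untreated lists and 1355, 3802 and 164 kb in the treated lists, a log2 ratio of 1.22 (exact permutation p = 0.8). Median peak width was 235 and 376 bp without the drug and 234, 323 and 243 bp with it. This gave a difference of -38.8 bp (exact permutation p = 0.6) that became 31.7 bp without untreated list 2. The narrowest peak was 199 and 332 bp wide in the untreated lists and 193, 291 and 200 bp in the treated lists. The lists ranked in the same order by narrowest and by median width. The medians therefore cannot be read as the width of binding alone, and the length covered depends on these widths too.

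The direction differed between the pairs of lists that shared a run identifier. In the pair of untreated list 1 and treated list 1 the treated sample had 2.13-fold more peaks, a log2 ratio of 1.09. In the pair of untreated list 2 and treated list 3 the treated sample had 528 peaks against 2039, a log2 ratio of -1.95. The mean log2 ratio over these 2 pairs was -0.43, opposite in sign to the pooled 1.25. The pooled value is a log2 ratio of group means and includes treated list 2. The treated list covered 2.14-fold more in the first pair and 5.44-fold less in the second, a mean log2 ratio of -0.67 against the pooled 1.22. The mean difference in median width over the pairs was -67.0 bp. The medians, untreated then treated, were 235 and 234 bp in the first pair and 376 and 243 bp in the second. Each pair holds 1 list per group, so neither could be tested. Without treated list 2, which has no partner, the log2 ratio of the group means was -0.0036 for covered length, with the remaining treated lists at 1355 and 164 kb, and 0.32 for peak numbers.

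**Figure D1:**
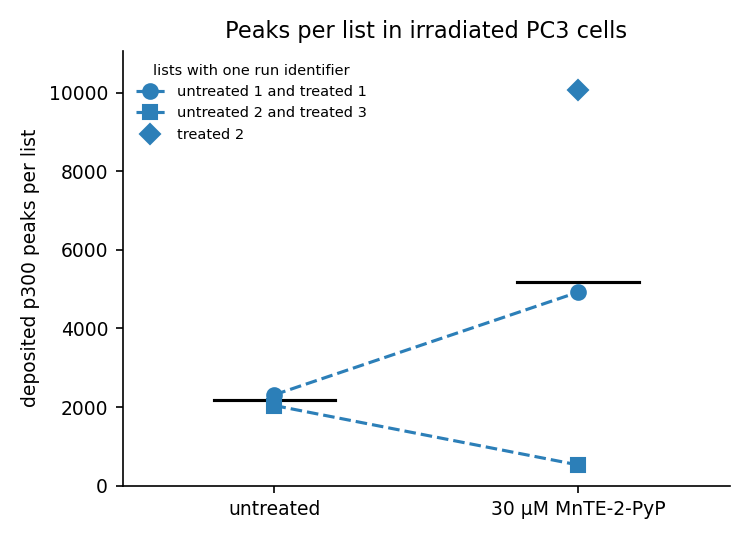
Number of deposited p300 peaks (vertical axis) in each untreated and MnTE-2-PyP-treated list, with black bars at the group means of 2176 and 5170 and dashed lines between lists that share a run identifier. One line rises from 2313 to 4922 and the other falls from 2039 to 528.

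The next comparison asked whether lists of one group shared binding sites more than lists of different groups. The 5 lists merged into 16701 regions, of which 14959 (89.6%) were found in a single list. A further 1036 regions were in 2 lists, 366 in 3, 192 in 4 and 148 in all 5. Untreated lists 1 and 2 had 58.7% and 67.4% of their regions in no other list. Treated lists 1, 2 and 3 had 73.6%, 86.0% and 16.5%. The untreated lists overlapped each other least of all pairs, at 16.8% of the shorter list (95% Wilson interval 15.2 to 18.5%). Treated lists 1 and 2 overlapped at 21.2% (20.1 to 22.4%). Across the groups, untreated list 1 overlapped treated list 1 at 30.7% (28.9 to 32.7%) and treated list 2 at 32.0% (30.1 to 33.9%). Treated list 3, the shortest, overlapped the others at 38.8% to 73.9%.

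Every pair overlapped more than randomly placed peaks, which reached at most 0.947%, and more than shifted peaks, which reached at most 7.20%. Same-group pairs averaged 43.8% and between-group pairs 34.1%, a difference of 9.65 points (exact one-sided permutation p = 0.2). The difference rested on treated list 3, and without it same-group overlap was lower by 9.05 points (-9.05). With the 528 top-scoring peaks of each list the averages were 36.9% and 36.1% (exact permutation p = 0.4). At that equal length the lowest overlap, 21.0%, was between untreated list 2 and treated list 3, which share a run identifier, and the highest, 51.9%, was between treated lists 1 and 2.

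**Figure D2:**
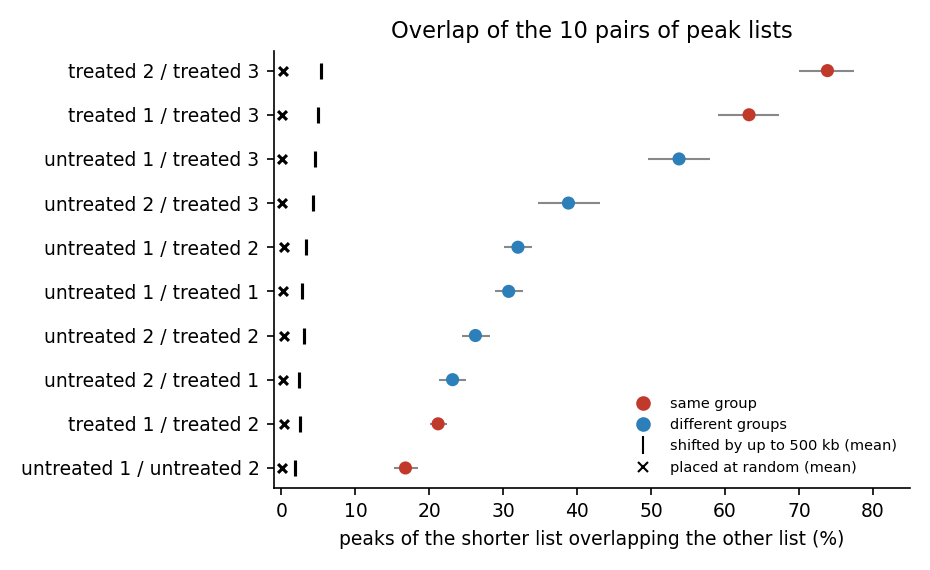
Percentage of peaks of the shorter list that overlapped the other list (horizontal axis) for the 10 pairs of lists, with 95% Wilson intervals, red for same-group and blue for between-group pairs. The bars and crosses near 0 are means over 100 shifted and 100 randomly placed sets, which every pair exceeds, and the same-group pairs lie at both ends of the range.

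Regions that followed treatment were then counted. Loss of p300 with MnTE-2-PyP would appear as regions in both untreated and no treated list, of which there were 31. They lay on 14 chromosomes, with 7 on chromosome 8 and 5 on chromosome 10. The highest-ranked were on chromosome X at 149588753 to 149589283, with scores of 11.8 and 13.9 in untreated lists 1 and 2, and on chromosome X at 115000317 to 115000680, with 15.8 and 7.52. They were followed by chromosome 2 at 205374191 to 205374561 (9.49 and 8.39), chromosome 8 at 115516682 to 115517149 (25.7 and 5.13) and chromosome 10 at 57387984 to 57388539 (11.1 and 5.93). The remaining 5 of the 10 named were on chromosome 2 at 243153727, chromosome 10 at 75205288, chromosome 1 at 121485070 and 142949541, and chromosome 19 at 8895042. Their median score percentile within a list was 52.7, so as a set they were peaks of middling score. Shifted peaks gave a mean of 9.92 such regions and at most 16.

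Gain of p300 would appear as regions in all 3 treated and no untreated list, of which there were 40. They lay on 16 chromosomes, with 7 on chromosome 1, 6 on chromosome 2 and 5 on chromosome 10, and their median score percentile was 62.8. The highest-ranked was on chromosome 13 at 39067878 to 39068189, with scores of 21.9, 11.0 and 13.7 in treated lists 1, 2 and 3. The next were on chromosome 8 at 122891426 to 122891727 (28.9, 8.29 and 14.2), chromosome 1 at 142897402 to 142897810 (14.1, 13.2 and 14.8), chromosome 20 at 29612135 to 29612454 (15.0, 13.3 and 12.5) and chromosome 8 at 102690369 to 102690935 (10.1, 11.3 and 15.6). They also included a region on chromosome 16 at 47538518 to 47538907 (9.34, 7.38 and 58.0). The other 4 named were on chromosome 2 at 223338205, chromosome 1 at 230067890, chromosome 15 at 71466749 and chromosome 12 at 13681101. Shifted peaks gave at most 3 such regions. A wider set, in 2 or more treated and no untreated list, held 489 regions, against at most 99 in shifted sets. None of the regions named here for loss or gain was checked for repeated sequence, because no annotation of hg19 was used.

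Other pairs of lists gave counts as large. For the 31 regions held by the untreated pair alone, 6 of the other 9 pairs had more, up to 375 for treated lists 1 and 2, the longest lists. The pairs with fewer, at 4, 7 and 25, all included treated list 3, the shortest. The ranking of full lists thus also reflects their lengths. For the 40 regions held by the treated lists alone, 3 of the other 9 sets of 3 lists had more, up to 153. For the 489 regions, 2 of 9 had more, up to 857. With equal numbers of top-scoring peaks the untreated pair alone held 7 regions, fewer than each of the other 9 pairs, which held 8 to 38. At that length all 3 treated lists alone held 16, a count reached by 3 of the other 9 sets, which held 3 to 39. The wider set held 105, reached by 1 of the other 9, which held 30 to 147. Leaving out a list loosens these definitions, except that leaving out a treated list tightens the widest, since both remaining treated lists must then hold the region. The 40 regions became 91 without untreated list 1, 90 without treated list 1, 67 without treated list 2 and 415 without treated list 3. The 31 regions became 1393 without untreated list 1, 1357 without untreated list 2, 52 without treated list 1 and 47 without treated list 2. The 489 regions became 745 without untreated list 1, 90 without treated list 1 and 67 without treated list 2.

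**Figure D3:**
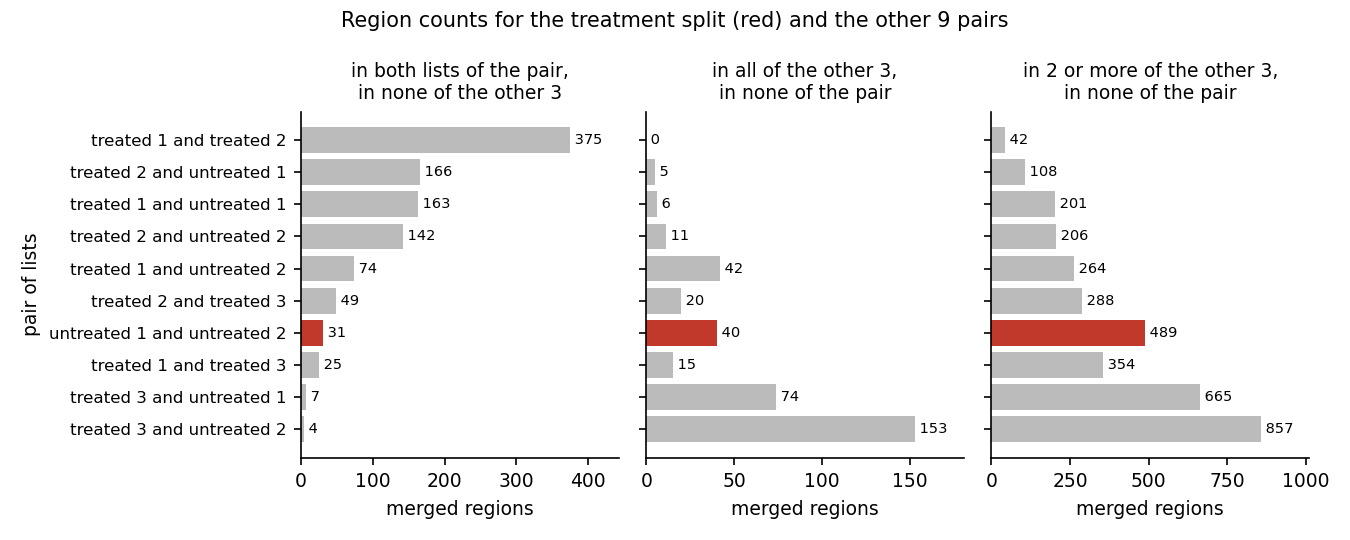
Merged regions (horizontal axes) held by both lists of a pair and by none of the other 3 (left), by all of the other 3 and none of the pair (middle), or by 2 or more of the other 3 and none of the pair (right), for each of the 10 pairs of lists. The treatment split, in red, gives 31, 40 and 489 regions and is not the largest in any panel.

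A set of 148 regions carried p300 peaks in all 5 lists, with and without the drug, and 268 were in all of the other 4 lists when treated list 3 was left out. Of the 148, 66 stood alone and 82 lay in 17 clusters. The isolated regions included the strongest recurrent peaks, and all 10 named by the rule were isolated. These were on chromosome 5 at 132702198 to 132702738, with scores of 55.1 and 40.6 in the untreated and 62.2, 69.7 and 26.1 in the treated lists, chromosome 6 at 126589344 to 126589818, chromosome 17 at 58024405 to 58024906, chromosome 1 at 195466603 to 195467120, chromosome 14 at 104210847 to 104211390, chromosome 16 at 72661668 to 72662137, chromosome 18 at 36225079 to 36225571, chromosome 20 at 15868342 to 15868848, chromosome X at 105713124 to 105713501 and chromosome 9 at 73504875 to 73505312. They were 378 to 544 bp wide. The chromosome 17 region held the highest score of untreated list 2 (52.6), and the chromosome 1 region that of treated list 2 (103.6). The highest-scoring peaks of the other lists were on chromosome 4 at 116458337 to 116458648 in untreated list 1 (105.1), chromosome 5 at 78619903 to 78620195 in treated list 1 (94.3) and chromosome 1 at 108113092 to 108113694 in treated list 3 (75.7).

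The 17 clusters of recurrent regions lay on 13 of the 24 chromosomes. A stretch of 114.4 kb on chromosome 8, from 86726466 to 86840885, held 15 of the 148 regions, with 32 and 20 peaks in the untreated lists and 38, 22 and 32 in the treated lists. A stretch of 69.9 kb near the end of chromosome 4, from 190942652 to 191012562, also held 15, and one of 17.3 kb near the end of chromosome 10, from 135477889 to 135495206, held 9. The ends of the long arms of chromosomes 4 and 10 are known to carry related tandem repeats. Further clusters were on chromosome 19 from 36773451 to 36798973 with 6 regions and chromosome 16 from 33935082 to 33964297 with 5. Another recurrent region lay within 50 kb for 55.4% of the 148, against at most 10.8% in 100 random draws of as many regions. Peaks in or near these clusters made up 9.68% and 6.92% of the untreated lists and 5.85%, 2.00% and 30.9% of the treated lists.

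**Figure D4:**
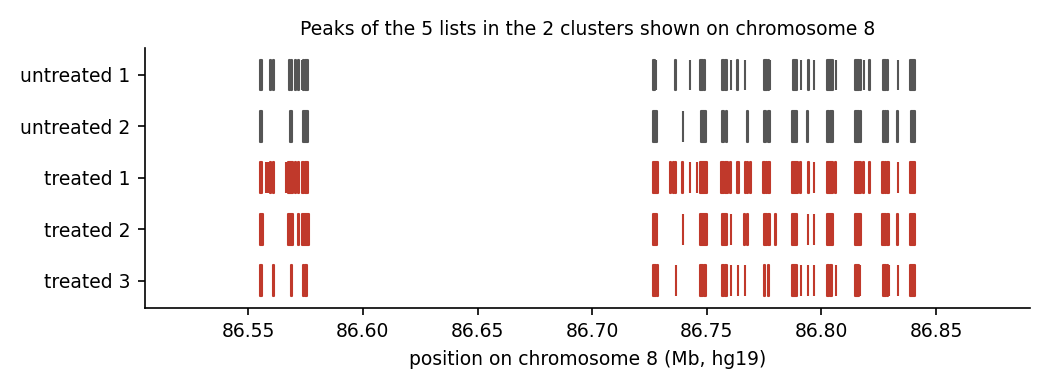
Peaks of the 5 lists (one row each, grey untreated and red treated) along chromosome 8 (horizontal axis, Mb in hg19) around the clusters from 86555062 to 86576293 and from 86726466 to 86840885. All 5 lists have peaks in both clusters, with 32, 20, 38, 22 and 32 in the second.

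The distribution over chromosomes was uneven in both groups. Chromosomes 1, 8, 10, 14, 15, 19 and 21 held more than their part of the genome span in all 5 lists, and chromosomes 2, 3, 6, 12, 13, 18, X and Y held less. Chromosome 10 makes up 4.52% of the span and held 12.9% and 9.61% of the untreated peaks and 16.3%, 7.02% and 9.28% of the treated peaks (exact permutation p = 1.0). Chromosome 8 makes up 4.71% of the span and held 9.43% and 9.22% of untreated peaks against 10.8%, 6.70% and 11.2% of treated peaks (exact permutation p = 1.0). Of 24 chromosomes, 1 reached the smallest possible exact permutation p of 0.2. This was chromosome 15, with 3.27% ± 0.391 of peaks in the untreated (SD, n = 2) and 3.78% ± 0.227 in the treated lists (SD, n = 3), while 4.8 chromosomes are expected to reach it by chance.

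Peaks were concentrated within chromosomes as well. The first 5 Mb of chromosome 1 held 2.64% and 2.94% of the untreated and 2.09%, 2.44% and 3.22% of the treated lists. These were 61 and 60 untreated and 103, 245 and 17 treated peaks. A recurrent cluster there, from 2584112 to 2629801, held 24 and 11 of the untreated and 38, 28 and 15 of the treated peaks. The share of treated list 3 thus lay mostly in that cluster. On chromosome 10, the stretch from 75 to 85 Mb held 158 and 82 untreated peaks, or 6.83% and 4.02% of the lists, and 452, 249 and 13 treated peaks, or 9.18%, 2.48% and 2.46%. On chromosome 8, the stretch from 140 to 145 Mb held 2.55% and 3.29% of the untreated lists and 2.78% and 2.72% of treated lists 1 and 2. Treated list 3 had 0 of 528 peaks there, which allows a share of up to 0.568%. Together the stretches on chromosomes 10 and 8, 15 Mb, make up 0.501% of the span. They held 9.38% and 7.31% of the untreated and 12.0%, 5.20% and 2.46% of the treated peaks (exact permutation p = 0.8).

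**Figure D5:**
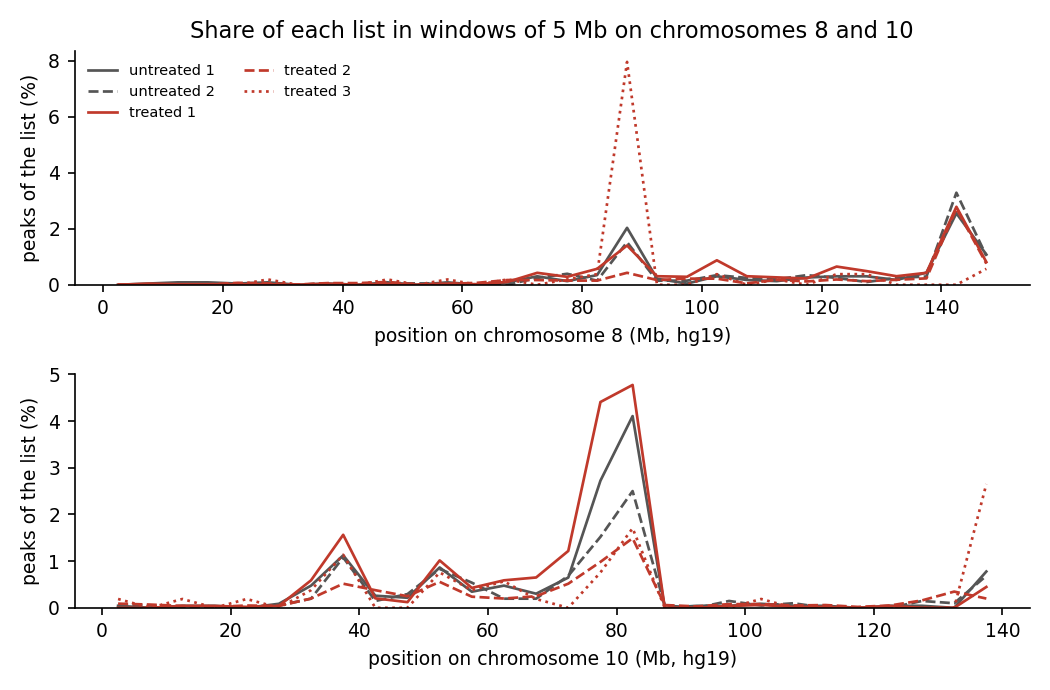
Percentage of the peaks of each list (vertical axes) in windows of 5 Mb along chromosomes 8 and 10 in hg19, grey for untreated and red for treated lists. Most lists peak at 140 to 145 Mb of chromosome 8 and at 75 to 85 Mb of chromosome 10, and treated list 3 holds 7.95% of its peaks in the window from 85 Mb of chromosome 8.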

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

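The tests of the score threshold and of a uniform change with the drug were chosen after the result was seen. The number of p300 peaks moved in opposite directions in the pairs of lists with one run identifier, with log2 ratios of treated over untreated of 1.09 and -1.95, and this difference was not tested because each pair holds 1 list per group. With one common score minimum of 3.04 the ratios were 1.09 and -1.96, still opposite in sign. It removed at most 6.44% of any list. Within each pair the lowest scores were already close, at 3.04 and 3.04 and at 2.02 and 2.16. These values argue against different minima of the deposited score as the source. The scale of the score is not named, so thresholds set on another measure stay open. A low yield of treated list 3 is a candidate explanation for its part of the pattern. The peaks of the other 4 lists that it shared lay at a median score percentile of 88.9 within their own lists. By list the median was 80.74 and 82.34 in untreated lists 1 and 2 and 90.63 and 94.55 in treated lists 1 and 2. This met the prediction for a low yield. It cannot decide on yield, because peaks shared by other pairs of lists were not ranked for reference. Nor was the ranking repeated without peaks in or near the recurrent clusters, which made up 30.9% of treated list 3. A drug-related loss that spares strong sites would also look the same. A uniform change with MnTE-2-PyP cannot be told apart from library differences, as the ratios differ by 3.04 on the log2 scale with no spread to set against it.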

How the results depend on the processing

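Of the alternative values, 64 kept their direction or, for counts, stayed within 1.5-fold, 20 counts moved further and 5 values changed sign. Requiring 50% overlap, merging within 500 bp, autosomes and X only, and group medians changed no direction and moved no count by more than 1.5-fold. The same held for one common score minimum, which removed at most 6.44% of a list. The removal of clustered regions left 30, 35 and 469 of the 31, 40 and 489 regions that followed treatment. The overlap and the regions in all 5 lists were not recomputed in that setting. Of these 148 regions 82 lay in clusters, so only 66 would remain, a change of more than 1.5-fold. Keeping the upper part of the pooled scores left 10 regions in both untreated and no treated list, 24 in all treated and no untreated list, 240 in 2 or more treated and no untreated list and 90 in all 5 lists. Equal numbers of top-scoring peaks left 7, 16, 105 and 71, a log2 ratio of covered length of 0.024 in place of 1.22 and a width difference of -12.8 bp in place of -38.8. Both settings hold fewer peaks, which lowers the counts. Leaving out 1 list changed these counts to 31 to 1393, 59 to 415, 67 to 745 and 149 to 268, because fewer lists then define each set. Over the same settings the log2 ratio of covered length ran from -0.0036 to 1.76, the difference in median width from -109.3 to 31.7 bp and the overlap difference from -9.05 to 23.4 points. For the replicate block, lists with the same number gave log2 ratios of 1.70 for peak numbers and 1.60 for covered length and a width difference of -27.0 bp. Only the lists numbered 1 share a run identifier as well as a number, so the numbers do not pair the samples. Pairing by run identifier instead, an alternative chosen after seeing the data, gave -0.43 for peak numbers and -0.67 for covered length, both reversed. This setting leaves out treated list 2 and averages log2 ratios, while the pooled value is a log2 ratio of group means. For the same lists the log2 ratio of group means was 0.32 for peak numbers and -0.0036 for covered length. The mean of log2 ratios would be the same however these lists were paired, so the reversal is not an effect of pairing. The planned results on promoters, genes and gene lists were not run for want of an hg19 annotation. Depth is unknown, and it limits every statement on a peak missing from a list.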

Other observations

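Treated list 2, the longest, held peaks in places where the other lists held few. In 10 windows of 5 Mb with at least 30 of its peaks, its share was more than 2 times that of each other list. Over the highest other share the fold was 2.06 to 4.05. Such windows were not counted for another list, so their number has no reference. Counts of peaks in these windows also reflect the length of the list. The first 5 Mb of chromosome 7 held 108 of its peaks against 3 and 6 in the untreated lists and 6 and 1 in treated lists 1 and 3. By share this was 1.07% of the list, against at most 0.294% of any other. The last such window of chromosome 2, from 240 Mb, held 56 against 3, 4, 2 and 1 in the same order, and the window from 30 to 35 Mb of chromosome 1 held 40 against 2, 2, 4 and 0.

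Regions found again in several lists were clustered, and 1 test of this was written before its result was seen. Reads of repeated sequence gathered on few reference copies are a candidate explanation. PC3 is described as lacking a normal Y chromosome, so peaks placed there would come from reads of like sequence elsewhere. Of 108 peaks on Y, 54 were in regions of 3 or more lists, against 14.0% of 19753 peaks on the other chromosomes, a ratio of 3.58. One cluster on Y, from 13461707 to 13490082, held 34 of the 108 and 30 of the 54. Without it 24 of 74 (32.4%) were in such regions, a ratio of 2.32 chosen after the first was seen. Counted as regions, 13 of 57 on Y (22.8%) and 4.16% of the others were in 3 or more lists. The test bears on repeats in general and does not show that each cluster is one, and no biological explanation was tested.

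Dense stretches of peaks on chromosomes 10 and 8 were set against 2 explanations, with both tests written before their results were seen, on stretches chosen after their counts were seen. The first 5 Mb of chromosome 1 and the window from 85 to 90 Mb of chromosome 8, each with a mean share of 2.67% against 2.27% for the chromosome 8 stretch, were not among them. The density was present without MnTE-2-PyP, as the untreated lists held 9.38% and 7.31% of their peaks in these 0.501% of the span. The shares of treated and untreated lists overlapped, as predicted without a change with the drug, and the means differed by -1.80 points. This cannot exclude a change in the shares, because the lists are few and the treated shares ran from 2.46% to 12.0%. Raised background from extra DNA copies may explain the density but stays open. Peaks in these stretches recurred in another list 3.73 times as often as after shifts of up to 500 kb, against 8.37 times elsewhere, which met the prediction, but the excess in points was 22.7 there and 21.3 elsewhere, and the ratio falls with density by itself, so the prediction was a poor one. Values seen afterwards show steps along both chromosomes in every list: from 0 to 65 Mb of chromosome 8 the lists together held 1.28 peaks per Mb and from 65 to 145 Mb 17.8, and on chromosome 10 they held 32.6 per Mb from 30 to 85 Mb and 2.48 from 85 to 135 Mb. In treated list 3 the chromosome 8 step, from 3 to 53 peaks, lay mostly in the recurrent clusters, which held 39 of the 53 and left 14.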
